A study of Homo sapiens with 4 samples.

How the data were processed

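H3K27ac HiChIP libraries of primary human endometrial stromal cells were compared, 1 EPC and 1 vehicle library from each of 2 donors (4 libraries in all). Per the labels, cells were treated for 3 days and the libraries were made by a company with its own kit. Groups were taken from the treatment label and pairing from the donor code that the titles share. The donors were separate people, so p-values of fits with treatment as the only term measure the spread between 2 donors per treatment. In fits with donor as a block they measure how far the EPC effect differs between the 2 donors. With 4 libraries, the blocked fits rest largely on spread borrowed across genes, loops or bins.

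The authors deposited 1 loop list per library, not pooled. MACS2 2.2.9.1 and the genome build hg38 are named in the submitters' processing notes with no role or order, and the aligner and the loop caller are not given in the sources used here. Per the file headers, each deposited loop has a contact count of whole read pairs and the count of reads covering each anchor bin, neither of them normalized. The deposited values further hold a bias ratio for each anchor, the coverage of the bin over the library's mean for peak or other bins. The deposited tables also give a modelled contact probability as a fraction, an expected contact signal that equals this probability times 1 constant per library, and a p-value and q-value for each loop. That constant was read as the number of contacts that entered the authors' model and is called modelled contacts. From the values, bins are 10 kb, spans run from 20 kb to 2 Mb, every loop has a q-value under 0.01 and at least 5 contacts, and at least 1 anchor lies in a peak. The deposited q-values select loops separately in each library, so a loop missing from a list has an unknown count, not a count of 0, and no fold change is given for genes without a listed loop in some library. In the gene and list fits, and in counts of list members higher or lower, such libraries entered as 0. A loop not listed in a library likewise added nothing to that library's gene sums, also at genes with a listed loop in every library. Changes of gene contacts thus mix the number of loops listed with the contacts per loop.

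Gene names and positions came from an NCBI RefSeq table of the assembly GRCh38.p14, which has the coordinates of hg38, and 59083 of its 59792 genes were used. Mitochondrial genes, genes of chromosome Y and XIST were left out of the gene and list fits. The table gives no strand, so the planned window of 1 kb around transcription start sites was replaced by 1 kb around both ends of each gene, and contacts at the far end of a gene are included. Genes whose ends share a 10 kb bin have partly the same contacts, and the protein-coding neighbours of named genes are given with them or in 1 sentence.

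Contacts were summed per gene over its listed loops and tested with edgeR 4.0.16 (quasi-likelihood test, TMM factors, default filter on low counts, treatment as the only term) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 40176 loops listed in all 4 libraries were tested the same way on their contacts, and coverage of the 34855 bins listed in all libraries was tested as a measure added after the data were seen. The 14 gene lists, with 213 distinct genes of which some are shared between lists, were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and with an estimated correlation. Only the decidual list passed at the preset correlation, and no list did with an estimated correlation. Loops listed, loop spans and list overlaps were described without a test. Errors are standard errors of the fitted log2 fold change unless they are marked as SD.

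Gene lists, tests and the rule for named genes were fixed before the data were examined. The rule took the 12 genes of each direction with the lowest p among protein-coding genes that moved the same way in both donors, since none passed, 12 genes of decidualization whatever their result, up to 4 members of each list with the lowest p, and the 5 rising and 5 falling loops with the lowest p at a protein-coding gene end. Of the list members the text prints those with the lowest p and those past the threshold within their list. Regions, windows and non-coding genes were chosen after their values were seen.

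Donor pairing was checked by the correlation of same-donor libraries' deviations from their group means, which was 0.28 for gene contacts, 0.34 for loop contacts and 0.53 for anchor coverage. As same-donor libraries come from the same person, fits with donor as a block are given where they change a result.

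The fits were tested on simulated data drawn from the real means and library sizes. The draws had no listing threshold, whereas unlisted loops add nothing to the real gene sums, so recovery on the real data may differ. At the spread estimated here, the gene fit recovered 0% of 2-fold, 8.96% of 4-fold and 37.9% of 8-fold changes over 25089 genes. The loop fit recovered 7.46%, 76.1% and 100% over 40176 loops, the bin coverage fit 13.4%, 94.0% and 100% over 34855 bins, and the gene coverage fit 38.8%, 98.5% and 100% over 18486 genes. Contact counts come from read pairs after amplification, so their errors cover counting and the spread between libraries.

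Alternatives were DESeq2 1.42.0, no TMM factor, no filter on low counts or at least 10 contacts, a q-value 10 times stricter (0.001), 5 kb windows, numbers of loops in place of contacts, loops listed in all libraries, donor as a block, and leaving out each library, which leaves 1 library in a group, so that the spread comes from the other group and the lone library is assumed to vary alike. Added after seeing the data were modelled contacts as library size, whole gene bodies, genes with a listed loop in every library, the coverage fits, and offsets for anchor coverage (geometric mean or product) and for span class. Tables and plots were made with Python 3.11.15. The columns for mappability, GC content and restriction sites hold only 0 and were not used.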

Results

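H3K27ac HiChIP was measured in primary human endometrial stromal cells, the fibroblast-like cells of the uterine lining that turn into decidual cells under progesterone and cyclic AMP. HiChIP joins DNA ends that lie near each other in the nucleus and enriches them for a histone mark, here the H3K27ac mark of active promoters and enhancers. Cells of 2 donors, called A and B, were kept for 3 days with a hormone mixture called EPC or with 0.2% ethanol as vehicle. EPC holds estradiol at 10 nM, the progestin medroxyprogesterone acetate at 1 µM and dibutyryl cyclic AMP, a cell-permeable form of the second messenger, at 100 µM. Each donor gave 1 EPC library and 1 vehicle library, so each treatment had n = 2 and 4 libraries were compared. For each library the authors deposited a list of loops, each a pair of 10 kb bins with its contact count and the read coverage of both bins.

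The EPC lists were longer than the vehicle lists in both donors, but relative to modelled contacts this held in donor A alone. In donor A, 168564 loops were listed with EPC and 131679 with vehicle, a ratio of 1.28. In donor B the lists held 100647 and 77774 loops, a ratio of 1.29. The group means were 134606 ± 48024.6 loops with EPC and 104726 ± 38116.6 with vehicle (SD, n = 2), where the SD is the difference between donors, while the ratio within donors was alike (SD 0.00989 over 2 donors). An exact two-sided permutation of 2 against 2 libraries cannot go below p = 0.33. The listed loops held 4618561 contacts in donor A with EPC, 3470414 in donor A with vehicle, 2333850 in donor B with EPC and 1850672 in donor B with vehicle. The contacts that entered the loop caller's model numbered 11363630, 10115842, 6577159 and 3318426 in the same order. The vehicle library of donor B was therefore the shallowest, and 55.8% of its modelled contacts lay in listed loops against 40.6%, 34.3% and 35.5% in the other libraries. The EPC library was the deeper one in both donors, with 1.12 (A) and 1.98 (B) times the modelled contacts of the vehicle library. Loops listed per modelled contact had an EPC to vehicle ratio of 1.14 in donor A and 0.653 in donor B. The direction thus turned in donor B, and list length was not separated from depth.

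**Figure D1:**
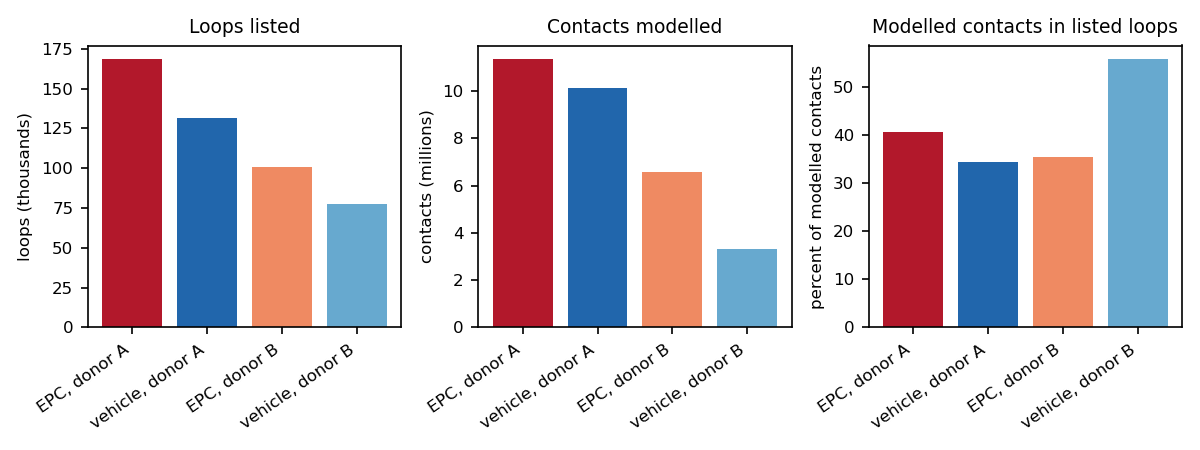
Bars show, for each of the 4 libraries, the number of loops listed, the number of contacts modelled and the percent of modelled contacts that lay in listed loops. The EPC lists were 1.28 times (donor A) and 1.29 times (donor B) as long as the vehicle lists, while the share in listed loops was 55.8% in the vehicle library of donor B and from 34.3% to 40.6% in the others. Per modelled contact, the EPC to vehicle ratio of loops listed was 1.14 in donor A and 0.653 in donor B.

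Loop spans were alike in both treatments and differed between donors. The median span was 100 kb in both donor A libraries and 80 kb in both donor B libraries. Loop lists were shared about as much by treatment as by donor. The Jaccard index, the loops in both lists over the loops in either, was 0.392 between the EPC libraries and 0.387 between the vehicle libraries, against 0.395 within donor A and 0.403 within donor B. With every list limited to its 77774 loops of lowest q-value the order turned, with 0.440 and 0.434 within treatments and 0.401 and 0.411 within donors. Contact counts of the 40176 loops listed in all 4 libraries ranked more alike within a treatment, with a Spearman coefficient across loops of 0.786 for the EPC pair and 0.768 for the vehicle pair, than within donor A (0.737) or donor B (0.689). Loops are not independent replicates, and no test was made of these indices. Of 240180 loops in any list, 15623 (6.50%) were in both EPC lists and no vehicle list, and 5723 (2.38%) were in both vehicle lists and no EPC list.

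After EPC, loop contacts rose around genes such as PDE10A, PRDM1 and LPAR1 and fell around RGMB and the keratin genes of chromosome 17. Of the 40176 loops tested, 412 rose and 422 fell (edgeR, adjusted p 0.05), each in the same direction in both donors. The median log2 fold change was 1.69 for loops that rose and -1.64 for loops that fell. The loops that rose had a median span of 60 kb and those that fell 105 kb, against 70 kb for all loops tested. An anchor at the end of a protein-coding gene was found in 279 of the 834 changed loops (33.5%), compared with 51.6% of the loops tested. With donor as a block the count was 4053 (1908 up, 2145 down), which kept all 834, and DESeq2 called 407. The count was 207 without the EPC library of donor A and 283 without the vehicle library of donor B, where the spread comes from the other treatment alone and the lone library is assumed to vary alike. Scaled by modelled contacts in place of listed contacts, edgeR called 0 loops (2310 at an unadjusted p under 0.05), the median of all loops shifted to -0.49, and all 834 loops kept their sign. The median went from 1.69 to 1.24 for the loops that had risen and from -1.64 to -2.20 for those that had fallen, and the median SE of the 834 was 0.77 there against 0.42.

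The gain with the lowest p at a gene end lay at PDE10A, which encodes a phosphodiesterase that breaks down cyclic AMP and cyclic GMP. The loop from chromosome 6, 165980001 to 165990000 (hg38), at the gene's end, to 166000001 to 166010000 beside it held 619 contacts with EPC and 38 with vehicle in donor A, and 421 and 14 in donor B (log2 fold change 4.23 ± 0.43 SE, edgeR adjusted p = 6.46e-08). Ends of the non-coding genes LINC00473 and LINC00602 lie in the same bin as that of PDE10A, so these contacts cannot be assigned to any single gene. Loops also rose at SLC46A3, a lysosomal transporter gene (chromosome 13, anchors starting at 28710001 and 28740001), by 2.45 ± 0.41 on the log2 scale, with 158 against 28 contacts in donor A and 104 against 16 in donor B. At BLK, a tyrosine kinase gene (chromosome 8, 11490001 and 11510001), the change was 2.30 ± 0.40. KCNJ8 and ABCC9, which encode both subunits of a potassium channel gated by ATP, were joined by a loop (chromosome 12, 21770001 and 21820001) that rose by 2.39 ± 0.42. A loop from TLE6 to its neighbour TLE2, both of the Groucho family of corepressors (chromosome 19, 2970001 and 3030001), rose by 2.52 ± 0.45. The edgeR adjusted p of these loops were 0.00063, 0.000837, 0.000896 and 0.000956 in that order.

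The loss with the lowest p lay at RGMB, which encodes a coreceptor for bone morphogenetic proteins. Its end bin on chromosome 5 (98760001 to 98770000) lost contacts with bins up to 660 kb away, in a stretch (98100001 to 98780000) that overlaps no other protein-coding gene. The loop to 98410001 held 9 and 12 contacts with EPC against 152 and 123 with vehicle (log2 fold change -3.81 ± 0.46, edgeR adjusted p = 6.13e-06). Loops to 98450001 and 98460001 changed by -3.12 ± 0.45 and -3.00 ± 0.45. In the keratin cluster of chromosome 17, a loop from KRT39 (40950001) to KRTAP2-3 and KRTAP2-4 (41060001) changed by -3.28 ± 0.43, with 19 and 14 contacts against 152 and 137 (edgeR adjusted p = 2.17e-05). A shorter loop, from 40910001 to KRT39, changed by -2.78 ± 0.39. Keratin and keratin-associated genes are close paralogs, so reads of this cluster could be split between copies.

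Changed loops lay in fewer regions than loops drawn at random. With anchors chained within 50 kb, they fell into 216 regions of rising and 181 of falling loops, and 19 regions of each kind held at least 5 loops. In 100 random draws of as many tested loops there were 342 to 373 and 348 to 379 regions, of which 0 to 3 held at least 5 loops. Neighbouring loops share anchors and so do not change independently, which the draws leave out. Loops rose around PRDM1, a transcriptional repressor gene (chromosome 6, 105480001 to 106100000, 11 of 51 tested loops), RHOB, a small GTPase gene (10 of 16), LPAR1, a lysophosphatidic acid receptor gene (10 of 32), the interleukin 1 receptor genes IL1R1, IL1R2 and IL1RL2 (9 of 25) and KLF9, a transcription factor gene (9 of 42). Contacts summed at the ends of KLF9 itself did not follow, at -0.14 ± 0.27. Loops fell around the keratin cluster (chromosome 17, 40900001 to 41550000, 18 of 58), RGMB (17 of 18), CPEB2 (15 of 29), THBS1, which encodes thrombospondin (13 of 139), the cytokine genes TNFSF4 and TNFSF18 (11 of 51), SOCS1, a suppressor of cytokine signalling (9 of 37), the collagen genes COL6A1 and COL6A2 (8 of 19) and the growth factor gene TGFB2 (7 of 17). These regions held no changed loop of the opposite sign. Of the regions with at least 5 loops, 3 did: at KLF6 a falling region (7 of 161, with 3 opposite) overlapped a rising one (5 of 167, with 5 opposite), and the rising region at IRS1 (7 of 118) held 2 that fell. Regions named here were chosen after the values were seen.

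Among windows of 1 Mb, those with FOXO1 and RGMB held the most loops listed with 1 treatment alone. FOXO1 encodes a transcription factor needed for decidualization. Among 2490 windows of 1 Mb with a loop, the window of chromosome 13 from 40000001 to 41000000, which holds FOXO1, had the most loops listed in both EPC libraries and neither vehicle library, 118 of 365 (32.3%, against 6.50% of all loops). Windows at IRS1, an insulin receptor substrate gene (98 of 686, 14.3%), and PRDM1 (84 of 490, 17.1%) followed among the first 4. The window with RGMB had the most loops listed in both vehicle libraries and neither EPC library, 79 of 266 (29.7%, against 2.38% of all loops), and that with NGF had 30 of 140 (21.4%). Such loops were spread over many windows: the EPC kind outnumbered the vehicle kind in 1538 windows, and the reverse held in 401. From 39700001 to 40800000 on chromosome 13, 395 and 257 loops were listed with EPC, at a mean of 31.5 and 23.3 contacts, against 67 and 18 with vehicle, at 14.9 and 13.0. Few of these loops touched FOXO1 itself: 21 and 22 with EPC, and 10 and 4 with vehicle, had an anchor at an end of the gene. A loop that is not listed has an unknown count, the EPC lists were the longer ones, and these windows were ranked after the data were seen with no test.

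**Figure D2:**
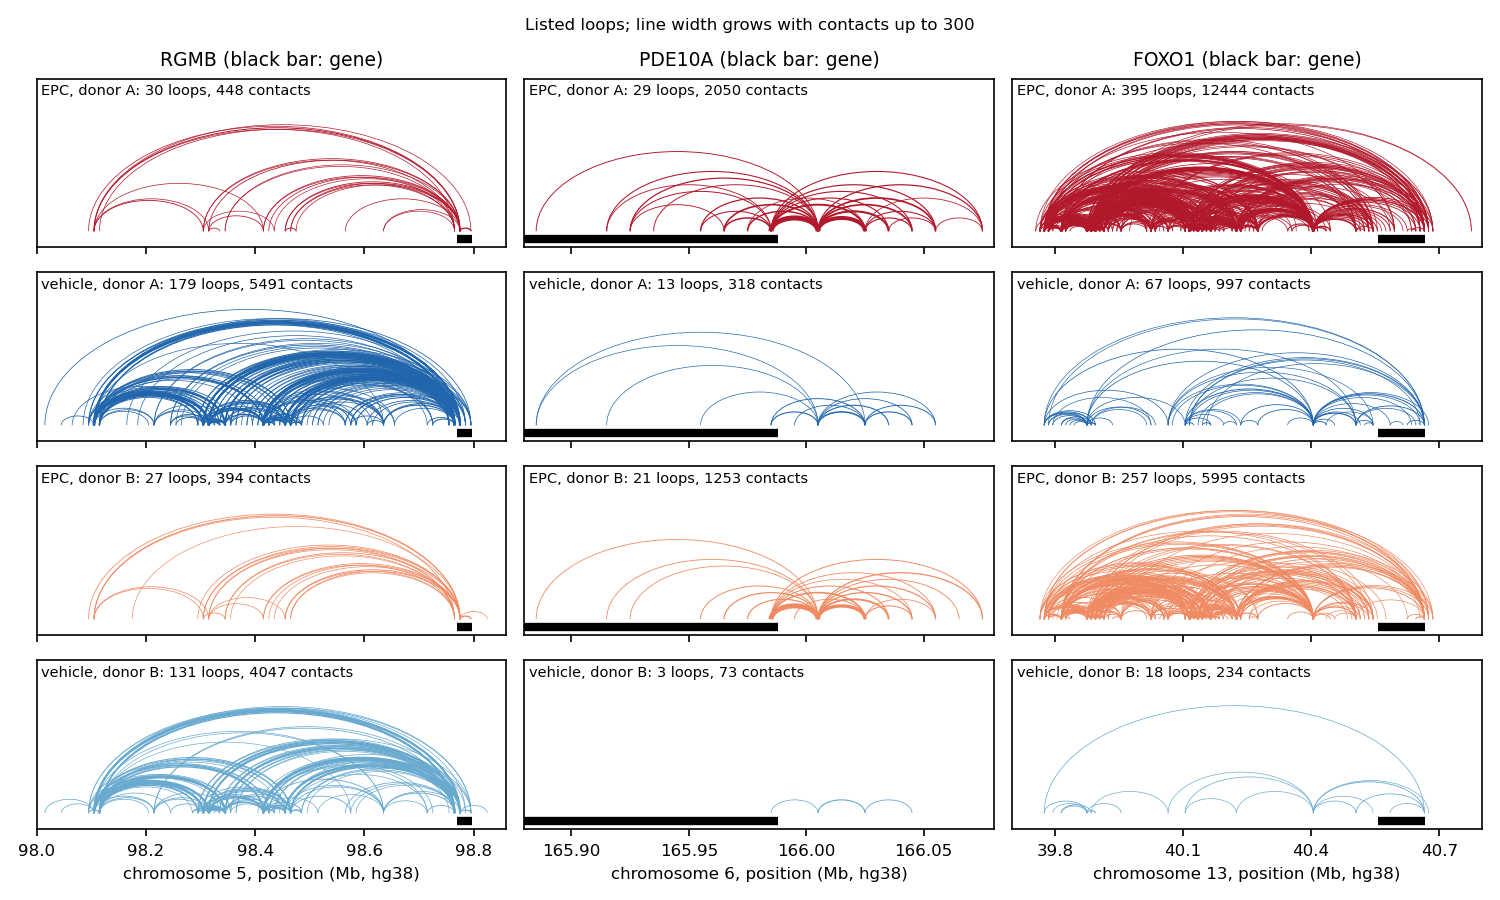
Arcs join the anchors of each listed loop in regions of chromosomes 5, 6 and 13 (position in Mb, hg38) for the 4 libraries, and line width grows with contacts. The RGMB region held 30 and 27 loops with EPC against 179 and 131 with vehicle, the PDE10A region 29 and 21 against 13 and 3, and the FOXO1 region 395 and 257 against 67 and 18 (donor A, donor B). In the FOXO1 region, 21 and 22 loops with EPC and 10 and 4 with vehicle had an anchor at an end of the gene.

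Read coverage of the anchors went the same way as contacts at 831 of the 834 changed loops. Reads that cover an anchor can include those of the loop's own read pairs, so contacts and coverage are not independent. The share of such agreement among all loops tested was not computed. Coverage was tested after the files had been seen, over 34855 bins listed in all libraries, and 720 bins rose and 579 fell (edgeR, adjusted p 0.05). With donor as a block the count was 5495, without the EPC library of either donor it was 379 (A) and 325 (B), without the vehicle library of donor A 3219, and without that of donor B 0. With the geometric mean of both anchors' coverage as an offset, 28 loops passed, of which 20 were among the 834, and the median change of the 834 in their own direction went from 1.67 to 0.62. The PDE10A loop kept its call (1.11, edgeR adjusted p = 0.0325), and none of the other 9 loops named by gene did. With donor as a block and the same offset, 7 of these 10 loops and 146 of the 834 kept their call. With the product of coverage as the offset, 90 loops passed, 1 of the 834 was kept and 19 passed in the opposite direction, the median was -0.49, and the PDE10A loop turned to -2.02 (edgeR adjusted p = 0.0495), as 1 of these 19.

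**Figure D3:**
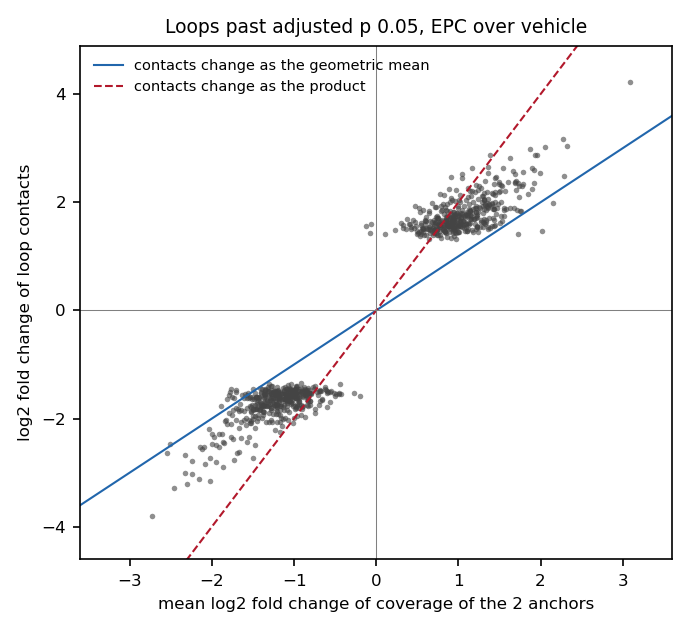
Each point is 1 of the 834 loops past the threshold, with the mean log2 fold change of the coverage of its 2 anchors on the x axis and the log2 fold change of its contacts on the y axis. Lines mark where contacts would change as the geometric mean (blue) and as the product (red, dashed) of the anchors' coverage, and most points lie near or between them.

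Contacts summed per gene had their lowest p among protein-coding genes at KRT39, IL1RL2, NGF and KRT23, and no gene passed the test over all genes. A gene's contacts were those of listed loops with an anchor within 1 kb of either end of the gene. Loops not listed in a library added nothing to its sum, also at genes with other loops listed. Of 25089 genes tested, 0 passed in edgeR (lowest adjusted p = 0.225), 2582 had an unadjusted p under 0.05, and DESeq2 called 1821. With donor as a block, edgeR called 119 genes (69 up, 50 down), 27 of them protein-coding. A gene with no loop listed entered as 0, and when only the 18798 genes with a listed loop in every library were kept, an alternative chosen after the data were seen, edgeR called 142 (83 up, 59 down) and with the block 1570. The fit over all 25089 genes recovered simulated 8-fold changes at 37.9% of genes and 4-fold changes at 8.96%, in draws without a listing threshold.

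The 12 protein-coding genes of lowest p with more contacts under EPC had main adjusted p values of 0.367 in edgeR. PDE10A, which shares an end bin with LINC00473 and LINC00602, had 1212 and 727 contacts with EPC against 63 and 14 with vehicle (log2 fold change 4.42 ± 0.52; 0.032 as the blocked adjusted p). IL1RL2, a receptor of the interleukin 1 family whose end bins also hold IL1R1, had 813 and 366 against 69 and 36 (3.08 ± 0.30; blocked 0.0336). COPS8, a subunit gene of the COP9 signalosome, and C9orf72, an endosomal and autophagy gene, changed by 2.87 ± 0.36 and 2.75 ± 0.32 (both blocked 0.0442). The number of loops listed enters these sums. COPS8 had 29 and 18 loops with EPC against 6 and 3 with vehicle, and C9orf72 27 and 15 against 6 and 4. Coverage at their ends changed by less, 1.10 ± 0.26 and 1.04 ± 0.25. For CMIP, MPHOSPH6 and P4HA3, a collagen prolyl hydroxylase gene that shares an end bin with PPME1, the values were 3.10 ± 0.43, 2.94 ± 0.45 and 2.08 ± 0.30. FAM135A and SDHAF4, which share end bins, both had 3.93 ± 0.60. RBM20, a splicing factor gene, had 200 and 124 contacts, ABCG1, a cholesterol exporter gene, 163 and 81, and ZDBF2 124 and 101, and no loop was listed at these 3 genes in either vehicle library. CMIP, MPHOSPH6, P4HA3, FAM135A, SDHAF4, ABCG1 and ZDBF2 did not pass with the block (blocked edgeR adjusted p 0.0515 to 0.0613). RBM20 passed (blocked 0.0458), with its unlisted vehicle loops entered as 0.

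Among the 12 with fewer contacts, KRT39 had 275 and 129 with EPC against 1911 and 821 with vehicle (-3.11 ± 0.28; blocked edgeR adjusted p = 0.0145). RGMB had 133 and 140 against 1659 and 960 (-3.49 ± 0.44; blocked 0.032). NGF, the nerve growth factor gene, had 164 and 107 against 957 and 614 (-2.89 ± 0.29; blocked 0.032), and SOCS1 258 and 141 against 828 and 449 (-2.04 ± 0.25; blocked 0.0458). The keratin gene KRT23 had -2.56 ± 0.29, and KRTAP2-2 and KRTAP2-3, which share an end bin, had -2.88 ± 0.36 and -2.94 ± 0.46, the latter also sharing with KRTAP2-4. SLC1A7, a glutamate transporter gene that shares an end bin with PODN, had -3.37 ± 0.39, EFL1, a ribosome assembly GTPase gene beside SAXO2, -3.33 ± 0.46, and ZNF475 with ZNF474 -1.68 ± 0.23. CDC42EP3 had -1.95 ± 0.28, and CNNM2 with NT5C2 -2.15 ± 0.33. The blocked edgeR adjusted p was 0.0442 for KRT23, KRTAP2-2 and SLC1A7, 0.032 for KRTAP2-3, 0.042 for EFL1 and 0.0361 for ZNF475. CDC42EP3 and CNNM2 did not pass with the block. Other named genes shared an end bin too: IGFBP1 with CCDC201, HAND2 with SCRG1, HOXA10 with HOXA9 and HOXA11, ZBTB16 with NNMT, ESR1 with SYNE1, RARA with CDC6 and GJD3, LOX with SRFBP1, COL6A2 with FTCD, FN1 with ATIC, THBS1 with FSIP1 and LOC124903470, CCND1 with LOC124902704, CD68 with EIF4A1, MPDU1, SENP3 and SOX15, and GAPDH with IFFO1 and NCAPD2.

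**Figure D4:**
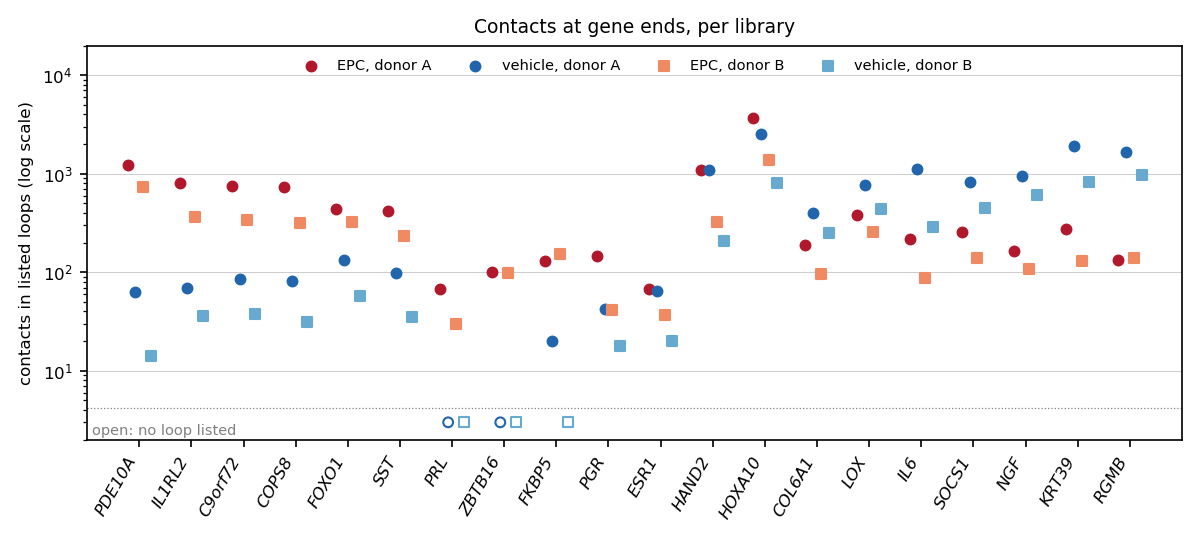
Contacts in listed loops at the ends of 20 genes, on a log scale, for each library, with open symbols where no loop was listed. PDE10A lies at 1212 and 727 with EPC against 63 and 14 with vehicle, and RGMB at 133 and 140 against 1659 and 960.

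Coverage at gene ends was tested on 18486 genes with at least 1 end bin listed in all libraries. Only such bins were summed, so a gene's coverage can leave out an end that its contacts include. Coverage changed at 95 genes (61 up and 34 down, edgeR adjusted p 0.05), 26 of them protein-coding. PDE10A rose (3.27 ± 0.45, adjusted p = 0.0153), as did IL1RL2 (2.00 ± 0.35), CMIP (1.92 ± 0.27), TLE6 (2.60 ± 0.42) and CEBPA, a transcription factor gene (1.55 ± 0.26). KRT39 fell (-2.27 ± 0.30, adjusted p = 0.0153), as did NGF (-2.12 ± 0.30), RGMB (-1.96 ± 0.27) and KRT19 (-1.39 ± 0.25). With donor as a block 2261 genes passed and DESeq2 called 650. Without the EPC library of donor A or B the counts were 209 and 259, without the vehicle library of donor A 246, and without that of donor B 16.

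Genes known to mark decidual cells passed as a group in some settings of the list test and not in others. The list moved up against all other genes in camera with a correlation of 0.01 (adjusted p = 0.0203) and did not pass with an estimated correlation (0.778) or over genes with a loop in every library (0.116). Of its 20 measured members 16 were higher and 4 lower, but 5 of the 16 had a library with no listed loop that entered as 0. SST, which encodes somatostatin, had 417 and 231 contacts with EPC against 99 and 35 with vehicle (1.98 ± 0.40), and FOXO1, the transcription factor gene, 440 and 321 against 132 and 57 (1.76 ± 0.37). The prolactin gene PRL had 67 and 30 contacts and the receptor gene SCARA5 had 73 and 25, with no loop listed in either vehicle library. BMP2 had 60 and 44 contacts against no listed loop in donor A and 10 in donor B, IGFBP1 23 and 23 against 14 and no listed loop, and WNT4 51 against 14 in donor A alone. HAND2 (-0.20 ± 0.59) and HOXA10 (0.25 ± 0.37), transcription factor genes of the stroma, showed values within their error. Of the 15 members with a loop in every library 11 were higher, with a median of 0.33. No member passed over all genes or adjusted over the list alone, though FOXO1 and SST passed adjusted over the list alone with donor as a block (adjusted p = 0.0313 for both). The list's adjusted p was 0.253 without the EPC library of donor B, 0.183 without its vehicle library and 0.256 for coverage.

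Targets of the hormone receptors and of cyclic AMP did not pass the test as groups, though PDE10A passed within its list. Of 14 measured progestin and corticoid receptor targets 10 were higher (camera adjusted p = 0.365), and ZBTB16, a zinc finger gene induced by progestins, had 100 and 98 contacts with EPC and no loop listed with vehicle. Its call adjusted over the list alone compares with unlisted loops entered as 0, whose counts are unknown, so the call is not counted as a result. FKBP5, a chaperone gene of steroid receptors, had 129 and 154 contacts against 20 and no listed loop. Of 14 cyclic AMP response genes 11 were higher (adjusted p = 0.212, and 0.028 without the EPC library of donor A), PDE10A passed adjusted over the list alone, and AKAP12, an anchoring protein gene of protein kinase A, had 0.84 ± 0.32. Coverage of this list gave an adjusted p of 0.012 with donor as a block, 0.0805 without it and 0.661 with an estimated correlation. Of 11 oestrogen receptor targets 8 were lower (adjusted p = 0.566), with RARA at -0.72 ± 0.34, PGR, the progesterone receptor gene, at 1.18 ± 0.66, and 0 past adjusted over the list alone. ESR1, the oestrogen receptor gene, had 68 and 37 contacts against 64 and 20 (0.05 ± 0.70), and GREB1 14 contacts in donor A with EPC and no other listed loop.

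Matrix and cell cycle genes had mostly fewer contacts under EPC, and inflammatory genes went both ways, and none of these lists passed. The lower values were not particular to these lists. Over members with a loop in every library, the median was -0.19 for matrix, -0.25 for cell cycle and -0.39 for housekeeping genes. Of 21 extracellular matrix genes 14 were lower (camera adjusted p = 0.123), with COL6A1 at -1.60 ± 0.29 and LOX, which crosslinks collagen, at -1.25 ± 0.28. None passed adjusted over the list alone, and 6 did so with donor as a block, all lower: COL6A1, COL6A2, LOX, COL1A1, FN1 and SPARC. Of 15 cell cycle genes 11 were lower (adjusted p = 0.566), with CCND1, which encodes cyclin D, at -1.76 ± 0.62 and past adjusted over the list alone with the block alone. Of 14 inflammatory genes 9 were higher (adjusted p = 0.615). Adjusted over the list alone, IL6 (-2.51 ± 0.48, 218 and 87 contacts against 1123 and 287) and LIF (-1.30 ± 0.31) passed as lower, and IL6 passed over all genes with the block (edgeR adjusted p = 0.0458). CXCL8 had 86 and 72 contacts with EPC and no loop listed with vehicle, and its call within the list rests on the same zeros as that of ZBTB16. Of 15 contractile genes 8 were higher (adjusted p = 0.566), where the median was 0.02, the mean -0.05 and the test direction lower. CALD1 (0.90 ± 0.33) and THBS1 (-0.87 ± 0.23) passed adjusted over the list alone with the block only.

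Markers of the stroma and of other endometrial cell types did not pass the test as groups. Of 15 stromal identity genes 7 were higher and 8 lower (camera adjusted p = 0.566), with PDGFRA at 0.80 ± 0.36. With the block PDGFRA, MEIS1 and EMX2 passed adjusted over the list alone, the first higher and the others lower. Of 8 measured epithelial markers 6 were lower (adjusted p = 0.421), KRT19 (-2.35 ± 0.48) passed adjusted over the list alone, and KRT7 stood at 1.41 ± 0.52. With the block KRT8, KRT18 and KRT19 passed as lower and PAX8 as higher. The 4 endothelial markers split 2 and 2 (adjusted p = 0.861), with CDH5 at -0.74 ± 0.57, and PECAM1, with 462 and 38 contacts against 55 and no listed loop, passed adjusted over the list alone with the block, again with an unlisted library entered as 0. The 6 leukocyte markers split 3 and 3 (adjusted p = 0.691), with CD68 at -0.61 ± 0.40 and 0 past. Of 11 smooth muscle and pericyte markers 6 were lower (adjusted p = 0.615), and KCNJ8 (1.93 ± 0.36) passed adjusted over the list alone. Of 11 housekeeping genes 7 were lower (adjusted p = 0.421), with GAPDH at -0.65 ± 0.26 and 0 past.

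**Figure D5:**
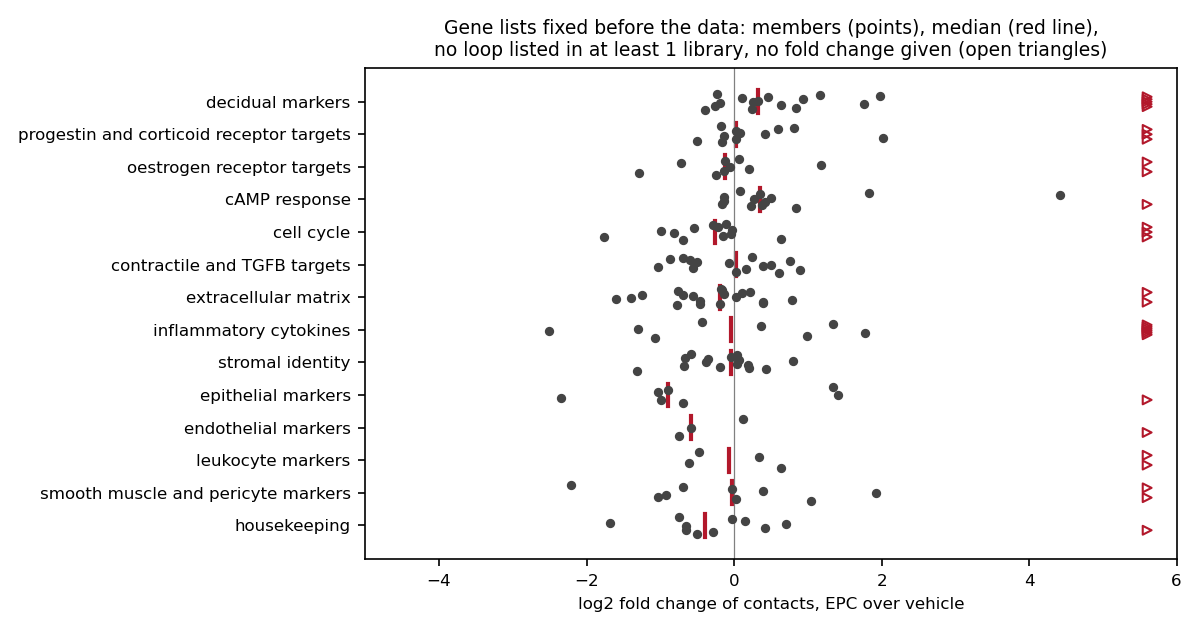
Points show the log2 fold change of contacts, EPC over vehicle, for each member of the 14 gene lists with a loop in every library, red lines their median, and open triangles at the right edge members with no loop listed in at least 1 library, whose fold change is not given. Of the decidual markers, 11 of 15 points lie above 0 with a median of 0.33, and 5 members are triangles.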

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

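The tests of sequencing depth, of enrichment and of the peak set were chosen only after the result was seen.

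The share of modelled contacts that lay in listed loops went opposite ways with EPC in the 2 donors. It was 1.18 times the vehicle share in donor A (40.6% against 34.3%) and 0.636 times in donor B (35.5% against 55.8%), and the difference between donors was not tested. The library that stood apart was the vehicle library of donor B. A different peak set per library is argued against, as all 64856 bins found in at least 2 lists carried the same peak flag. Low depth stays open, because modelled contacts are the denominator of the share and this library had the fewest (3318426) and the highest share (55.8%), while the other 3 do not rank by depth. Stronger enrichment in this library stays open as a candidate explanation too: its peak bins had 13.0 times the coverage of other bins, against 3.89 to 6.40 in the others, but those 3 do not rank alike in both measures, and with 1 library per donor and treatment a biological difference cannot be told apart from it.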

How the results depend on the processing

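Scaling by modelled contacts, the coverage fits, the offsets and the restriction to genes with a listed loop in every library were chosen after the data were seen. Where a value moved, the cause was not tested unless a test is named.

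The replicate block, with donor as the pairing, raised the number of calls at every level: 119 genes against 0, 4053 loops against 834, 5495 bins against 1299 and 2261 genes against 95 for gene end coverage. These blocked calls rest largely on spread borrowed across features. With anchor coverage as offset and the block 333 loops passed, against 28 with the offset alone. Over genes with a listed loop in every library the block gave 1570 genes against 142. With an estimated correlation, and over genes with a listed loop in every library, 0 gene lists passed with the block as without it. For gene end coverage 1 list, cyclic AMP response, passed with the block and 0 without it. Of 58 named genes 16 passed with the block, among them RBM20 with its unlisted vehicle loops entered as 0, and 0 passed without it. Adjusted within their list, 18 further genes passed with the block beside the 7 that passed without it. PECAM1 among the 18, and ZBTB16 and CXCL8 among the 7, rest on unlisted loops entered as 0. With anchor coverage as offset, 7 of the 10 named loops kept their call with the block and 1 without it. Apart from these and the directions given below, the block changed no other call.

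For gene contacts, DESeq2 called 1821, no filter on low counts 62, the number of loops per gene 51 and loops listed in all libraries 172. Leaving out any library called 0 genes, as did the whole gene body. For loops, DESeq2 called 407, modelled contacts as library size 0 (with a larger median SE, 0.77 against 0.42) and the product of anchor coverage as offset 90. For gene end coverage DESeq2 called 650. Leaving out each library in turn called 207 to 674 loops, 0 to 3219 bins and 16 to 259 genes by coverage. The lowest number of bins and of genes came without the vehicle library of donor B. The ratio of loops listed, 1.29, was 1.27 at the stricter q-value and 0.961 to 1.73 as libraries were left out, which by construction sets unequal shares of the donors against each other. Sharing within treatments less sharing within donors turned from -0.0092 to 0.0308 with lists of equal length.

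The number of gene lists past the threshold, 1, went to 0 with an estimated correlation, over genes with a listed loop in every library at either correlation (0 and 0), and for gene end coverage at either correlation (0 and 0). Leaving out libraries gave 0 to 2.

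Lists that changed direction had high adjusted p from camera throughout. For gene end coverage, alone, with the block and with an estimated correlation, the adjusted p was 0.755, 0.681 and 0.880 for oestrogen receptor targets, 0.230, 0.10 and 0.661 for inflammatory genes, and 0.743, 0.681 and 0.880 for smooth muscle and pericyte markers. Over genes with a listed loop in every library, with the same 3 settings, inflammatory genes had 0.676, 0.813 and 0.856. Endothelial markers turned with the block (0.899, and 0.959 with an estimated correlation). Leukocyte markers turned with 5 kb windows (0.824) and with the block over genes with a listed loop in every library (0.986). As libraries were left out, the lists that turned in at least 1 case had adjusted p of 0.293 to 0.945 (contractile), 0.432 to 0.945 (inflammatory and smooth muscle) and 0.640 to 0.945 (endothelial).

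Of the named genes, ESR1 turned to -0.090 with modelled contacts as library size. Leaving out libraries moved ESR1 from -0.32 to 0.57, HAND2 from -0.78 to 0.83 and HOXA10 from -0.12 to 0.76. Every other one of the 58 kept its direction in every fit of contacts. Coverage at gene ends went the other way from contacts at 2 of the 71 genes of the naming rule with both measures, CXCL12 (contacts -1.30, coverage 0.15) and TEK (0.13 and -0.26).

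All 10 named loops turned with the product of anchor coverage as offset. The log2 fold changes were -2.02 (PDE10A, the only one past the threshold after turning, edgeR adjusted p = 0.0495), -0.65 (SLC46A3), -1.32 (BLK), -0.61 (KCNJ8) and -1.11 (TLE6) for loops that had risen. They were 1.36, 0.92 and 1.38 (RGMB to 98410001, 98450001 and 98460001), 1.23 (KRT39 to KRTAP2-3) and 1.32 (the shorter KRT39 loop) for loops that had fallen. No named loop turned in any other fit or with any library left out.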

Other observations

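The gene set of the first paragraph and the tests of span and of epithelial markers were chosen after the results were seen, while the predictions for coverage and for keratin paralogs were written before those tests were run.

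Among genes with a listed loop in every library, non-coding genes of chromosome 13, in the same 1 Mb window as FOXO1, had the lowest p. FOXO1 itself lies from 40555667 to 40666641, and whether the contacts of these genes reach it was not tested. LINC00548 (chromosome 13, 40194509 to 40220502), a long non-coding RNA gene, had 1564 and 1143 contacts with EPC against 32 and 17 with vehicle (log2 fold change 5.50 ± 0.40, edgeR adjusted p = 0.000164). The pseudogene CDKN2AIPNLP3, farther from FOXO1 on the same side, had 1493 and 975 against 37 and 36 (4.68 ± 0.41). The long non-coding RNA gene LINC00473 shares an end bin with PDE10A and had 4.51 ± 0.47 (edgeR adjusted p = 0.00221), and LINC02836 near PRDM1 had 3.44 ± 0.45. In the RGMB stretch, the pseudogene MTCO1P24 had 52 and 39 contacts against 1139 and 826 (-4.78 ± 0.39, edgeR adjusted p = 0.000282).

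Changes in loop contacts could follow from H3K27ac coverage of the anchors, since HiChIP reads pile up where the mark is. Coverage can also include the reads of the contacts themselves, an overlap that the comparisons below do not remove. In each donor the 834 loops with the strongest change relative to counting noise were picked and measured in the other donor, where 793 (picked in A) and 797 (picked in B) went the same way. There the contacts changed by more than the geometric mean of anchor coverage, with a median excess of 0.25 on the log2 scale in both donors (0.249 in B, 0.246 in A), so that scaling alone is argued against. They changed by less than the product of coverage, by -0.557 (B) and -0.437 (A). The prediction for the product as the cause allowed contacts to change by less than it, so it was met in both donors. As it could not fail on that side, this lends the product no support. Exact scaling as the product was not seen: in each donor 138 of the 834 loops changed by more than it. Anchor coverage therefore stays open as a candidate explanation, with a scaling between the geometric mean and the product. A difference between libraries in how contacts fall with span is argued against, since 627 of the 834 loops called over both donors were kept with the span class as offset.

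Lower contacts and coverage at the keratin genes of chromosome 17 might come from reads shared between keratin paralogs. In the interval from 40900001 to 41420000 all 21 bins with a keratin gene had lower coverage (median -1.03), and the 5 bins without one had a median of -1.10, with a notch from -2.05 to -0.15. Of these 5 bins 4 were lower, and 2 passed as lower and 0 as higher (edgeR). The interval was bounded by the outer anchors of loops called as falling at keratin genes, so its bins were partly picked for a fall. With that choice, 5 bins and this notch, the test cannot decide and the explanation stays open. Fewer epithelial cells in the EPC cultures stays open too: 5 of 7 measured epithelial markers had lower coverage, from KRT19 (-1.39 ± 0.25), itself a keratin gene of chromosome 17, to PAX8 (1.44 ± 0.50 SE). Without KRT19, and with KRT8 and KRT18 counted once because they share bins, the median was -0.42 with a notch from -1.05 to 0.21.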
